A study of Mus musculus with 4 samples.

How the data were processed

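RNA sequencing measured transcripts in endothelial cells sorted from the cardiac ventricles of C57BL/6 mice as cells positive for both eGFP and CD31. Per the labels' protocols, a tamoxifen-inducible Cre driven by Tie2 regulatory sequence switched on an eGFP reporter and, in the Gata4 KO group, recombined loxP-flanked Gata4. Tamoxifen chow at 40 mg/kg body weight was given from 4 weeks of age for 4 weeks, and cells were isolated at 8 weeks. The 4 libraries, 2 control and 2 Gata4 KO, were all from sequencing run 2110. Groups were taken from the labels. Replicate numbers only follow the order of deposition, so no library was paired with another. The labels do not say whether the libraries of a group came from separate animals. Names of control libraries join several numbers and those of Gata4 KO libraries do not. Pooling, if any, may therefore have followed the groups and could not be told apart from genotype. The p-values measure the spread between these libraries, which may be partly technical.

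The authors deposited log2 values per library in a pair of tables, with genes higher in Gata4 KO in the first and all others in the second. Per the file headers, the tables are a fold-change export on an Ensembl annotation. The genome build was mm10 per the submitters' processing notes. Aligner, quantification, the unit before the logarithm and library normalization are not given in the sources used here, and sequencing depth is unknown, so no interval or limit that needs read counts was computed. The deposited log2 values were centred by gene: in each gene the median of the 4 libraries was 0 within a tolerance of 1e-05. Expression levels were therefore lost, and only differences between libraries of the same gene can be read. Ties occurred at a gene's lowest value and nowhere else (tolerance 2e-06), with 1011 genes tied in 2 libraries and 1565 in 3, as a lower threshold applied before the logarithm would leave. A fold against a group tied at that lowest value is given as "at least", and such genes enter list medians at that bound. The tie hides the spread of that group, so the standard error and p of such a gene may be too small. A ranking by p then favours these genes.

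Both tables were joined, giving 38087 Ensembl genes. Of these, 23617 had the same value in all 4 libraries and were not tested, which left 14470. The authors' deposited log2 fold change equalled the difference of group means to within 3e-07. Coordinates come from GENCODE M21 on the same build, which matched 36308 of the gene identifiers and 14202 of those tested.

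Gata4 KO was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 14470 genes and a threshold of 0.05. The design written before the data were examined had an eBayes mean trend for log-scale values. It was left out because the mean of a median-centred gene is not an expression level. That choice was made before any test was run, and the fit as first planned, which called 27 genes, is given as an alternative. In data simulated with no changed genes and centred in the same way, the fit without trend gave 0.93 times the expected number of genes at p of 0.001 and the fit with trend 1.47 times. This simulation was run after both counts were known. In all simulations here the values had no shared lowest value, and their variances were drawn from the fit without trend. The comparison therefore leans to that fit, and recovery among genes with tied libraries was not tested. The prior degrees of freedom were 2.96, beside 2 residual degrees of freedom. Tested on simulated data with 200 changed genes among 14470 in 20 runs, the test recovered 0% of genes planted at 2-fold and 0% at 4-fold, and 81.5% at 8-fold, with 7.8 false calls per run at that size. At an unadjusted p of 0.05 it recovered 73.6%, 95.9% and 98.8%.

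Lists of genes numbering 28, with 567 symbols of which 510 were tested, were fixed before the data were examined. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera uses only the 2 residual degrees of freedom, so hardly any list could pass, whatever its correlation. Endothelial identity, with an estimated correlation of -0.0328, went from an unadjusted camera p of 0.0121 at the preset to 0.108. A high p with an estimated correlation therefore cannot tell whether a list differs. A low p at the preset may in turn be too small where members varied together by more than 0.01. Estimated correlations were 0.62 for fibroblast, 0.55 for cardiomyocyte, 0.32 for macrophage and 0.23 for lymphatic markers. In simulations, camera called a list of 20 independent genes planted at a log2 difference of 0.5 in 20 of 20 runs. Lists whose members vary together were not simulated, nor were false calls of unchanged lists. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list. The genes named were Gata4, up to 12 in each direction and the 2 members of each list with the largest difference. The 12 were to be those past the threshold with the largest changes. Because fewer than 5 passed in each direction, the 12 with the smallest p whose groups did not overlap took their place, without predicted genes. The level condition of that rule could not act on centred values. A gene that the rule selects is not reported here. All other genes named, including further list members given as examples, were chosen after their values were seen. Permutation tests were exact for single genes and used 1e+05 resamples for a difference between lists.

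Alternatives planned beforehand were median-of-ratios scaling, quantile normalization, adjustment over all listed genes, other thresholds, the other set tests and leaving out each library in turn, where the remaining library of a group is assumed to vary like the other group. Chosen after seeing the data were leaving out genes with tied libraries, genes above the shared lowest value in only 1 library, and genes of chromosomes X and Y. Every Ensembl identifier was tested on its own. Joining and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.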

Results

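Transcript levels were compared between 2 libraries of Gata4 KO and 2 libraries of control endothelial cells from healthy mouse hearts. Gata4 encodes a zinc-finger transcription factor of heart development. The comparison asked how the transcript profile of cardiac endothelial cells differs in the group labelled Gata4 KO. Values are log2 values relative to each gene's median over the 4 libraries, and the depth of the libraries is unknown. Of 38087 listed genes, 14470 varied between libraries and were tested.

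The 2 Gata4 KO libraries had lower values for genes of fibroblasts, lymphatic endothelium, endocardium and macrophages than the 2 controls, and higher values for immediate early genes. The fibroblast list had a median log2 difference of -1.45, the lymphatic list -1.58 and the immediate early list 0.71. Each of these lists passed a set test at a preset correlation and none with an estimated correlation (adjusted p = 0.400 with an estimated correlation for each but macrophages, at 0.406). With 2 residual degrees of freedom, the test with an estimated correlation could hardly pass any list. The preset p may be too small, because members of these lists varied together (estimated correlations of 0.13 to 0.62, against a preset of 0.01). Neither test settles whether these lists differ. No single gene passed an adjusted p of 0.05, so the single genes below are given as values. Libraries of the 2 groups also differed in sex-linked transcripts, with Xist at least 63.9-fold higher in Gata4 KO and 4 Y-linked genes above their lowest value in the controls only. This is the pattern of male controls and female Gata4 KO animals, so sex and genotype cannot be told apart in any difference given here.

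Gata4 itself (ENSMUSG00000021944, mm10 chromosome 14, 63198922 to 63271692, protein coding) lay at 0.31 ± 0.25 in controls and -0.30 ± 0.23 in Gata4 KO (SD, n = 2 each). Both Gata4 KO values, -0.14 and -0.46, were below both control values, 0.48 and 0.14, in the direction of the labels. Of all tested genes, 17.3% lay below both controls, so this order alone does not show the deletion. The endocardial list, which includes Gata4, had a median of -0.85, lower than the difference of Gata4. The difference was 1.52-fold, with a log2 value of -0.61, a standard error of 0.26 and an adjusted p of 0.663 by limma. An exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. The value covers the whole gene, and the labels do not say which part was deleted.

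**Figure D1:**
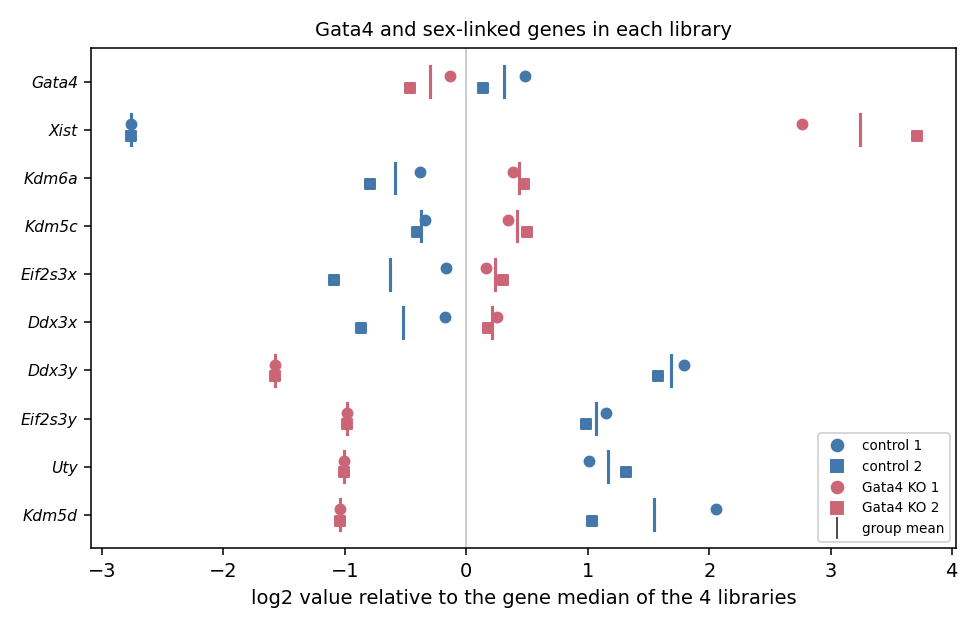
Values of Gata4 and sex-linked genes in each library (x axis, log2 value relative to the gene's median over the 4 libraries). Each point is a library and each vertical bar a group mean. Gata4 is separated by a log2 difference of -0.61, Xist by 6.00 in the opposite direction, and the 4 Y-linked genes lie at a shared lowest value in both Gata4 KO libraries.

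Xist (chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in female cells, was at the lowest value in both controls and at 2.76 and 3.71 in the Gata4 KO libraries (log2 difference 6.00, standard error 0.37, limma adjusted p = 0.0582). The Y-linked gene Ddx3y, an RNA helicase gene, was at least 9.62-fold lower in Gata4 KO (log2 difference -3.27, adjusted p = 0.0582). Eif2s3y, Uty and Kdm5d, chosen after values were seen, were tied at their lowest value in both Gata4 KO libraries, with log2 differences of -2.06, -2.17 and -2.58. Their X-linked counterparts Kdm6a, Kdm5c, Eif2s3x and Ddx3x differed in the opposite direction, by 1.02, 0.79, 0.86 and 0.74. Reads shared between Xist and its antisense gene cannot be excluded. The sex of the animals is not in the labels used here.

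Among genes with lower values in Gata4 KO, the smallest p belonged to Myl7 (ENSMUSG00000020469), which encodes the atrial myosin light chain. Both Gata4 KO libraries were at its lowest value, at least 25.7-fold below the controls (log2 difference -4.69, standard error 0.23, limma adjusted p = 0.0582). As in the other genes given as "at least", the tied group shows no spread, so the standard error and p may be too small. Sln, which encodes the calcium pump regulator sarcolipin, was at least 9.84-fold lower (adjusted p = 0.0582), and Fgf1, a growth factor gene, at least 5.37-fold lower (adjusted p = 0.110). Ptgs2, which encodes the prostaglandin-forming enzyme cyclooxygenase 2, was 5.66-fold lower, with values of 1.38 and 1.20 in controls against -1.20 and -1.23. Igfbp6, which encodes a binding protein of insulin-like growth factors, was 5.60-fold lower. Abhd1, Slamf9 and Kcnt2 were 5.34-, 4.32- and 4.597-fold lower, and the matrix gene Abi3bp at least 6.77-fold lower. AL935177.1 and RNaseP_nuc, at least 11.2- and 19.2-fold lower, are small RNAs of multi-copy families and are uncertain.

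With higher values in Gata4 KO stood Apol10b, 6.61-fold (log2 difference 2.72, standard error 0.21, adjusted p = 0.0870), and the endothelial early response gene Apold1, 3.80-fold (adjusted p = 0.266). Egr3, an immediate early transcription factor gene, was 3.87-fold higher and Sik1, a salt-inducible kinase gene, 3.16-fold higher (adjusted p = 0.297 each). Sfn, which encodes the protein 14-3-3 sigma, was at least 3.19-fold higher. The small RNAs snoU83B (17.7-fold), SNORD88 (at least 10.6-fold), Scarna3b (3.45-fold), mmu-let-7f-1 (2.55-fold) and Y_RNA (5.38-fold) belong to families with near-identical copies, and AC158898.2 (3.44-fold) is antisense to another gene, so these 6 are uncertain.

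**Figure D2:**
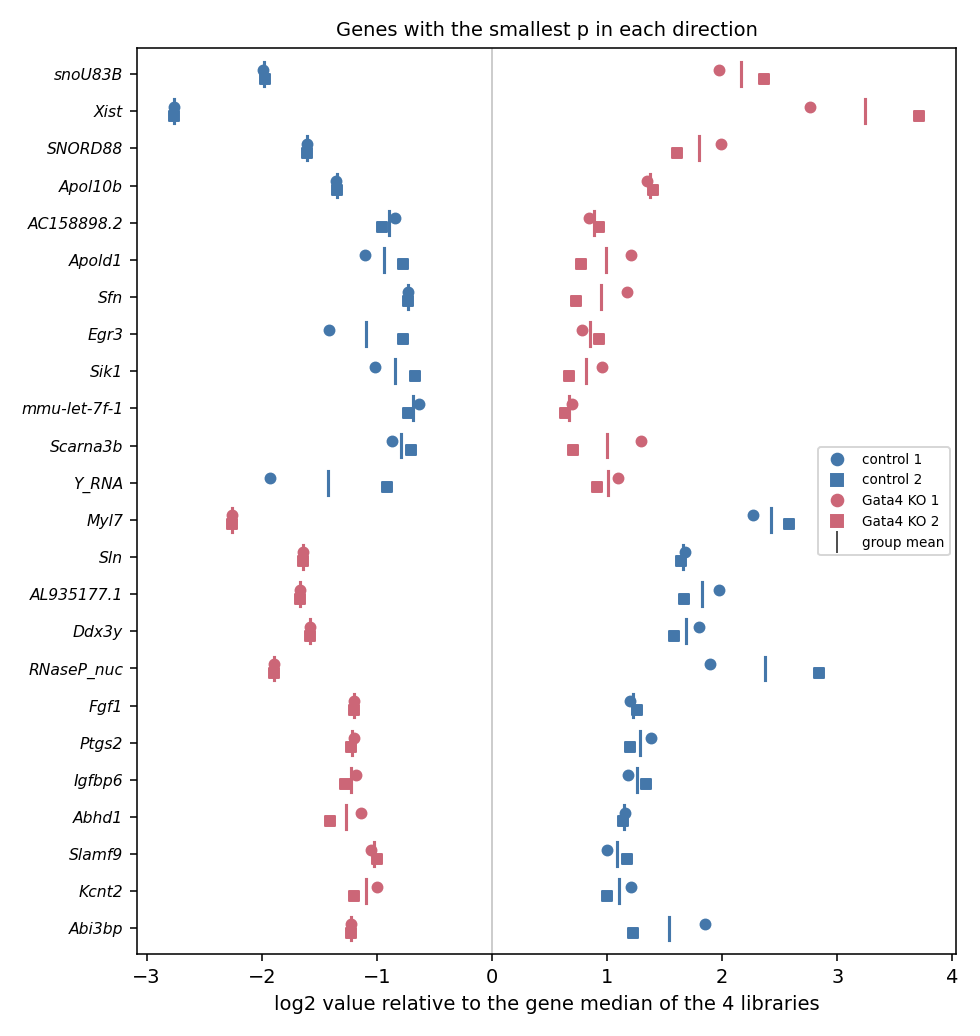
Values per library of the 12 genes with the smallest p in each direction among genes whose groups do not overlap and that are not predicted genes, which leaves out 1700066J24Rik (x axis, log2 value relative to the gene's median over the 4 libraries). Points are libraries and vertical bars group means. None of these genes passed an adjusted p of 0.05.

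By limma with Benjamini-Hochberg adjustment, 0 genes passed 0.05 and 9 had an adjusted p under 0.1. At an unadjusted p of 0.05 there were 399 genes higher and 776 lower, where 723.5 in all would be expected by chance. The fit with a mean trend, as first planned, called 5 higher and 22 lower. At the unadjusted p, leaving out control 1 gave 1069 genes higher and 1116 lower, Gata4 KO 1 495 and 497, and Gata4 KO 2 379 and 444, so the excess of lower genes was smaller in each; without control 2 there were 522 higher and 1547 lower. In the authors' deposited table, 234 genes were higher and 520 lower by a log2 fold change of at least 1.

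Fibroblast markers were lower in Gata4 KO in every member tested: all 18 had both Gata4 KO values below both controls, where chance gives 16.7% for a single gene. The members varied together (estimated inter-gene correlation 0.62), so the 18 are not separate observations. The matricellular gene Postn had a log2 difference of -1.78 (standard error 0.23), the microfibril gene Mfap4 -2.06 (0.32), the proteoglycan gene Dcn -1.90 (0.48) and the fibroblast transcription factor gene Tcf21 -1.47 (0.28). None passed over all genes, and 8 passed lower adjusted over the list alone. The list passed camera (adjusted p = 1.8e-13), and had an adjusted p = 0.400 with an estimated correlation. The mean over the list was 1.13 in control 1, 0.38 in control 2, -0.34 in Gata4 KO 1 and -0.88 in Gata4 KO 2. Among matrix genes outside this list, the basement membrane and extracellular matrix list did not pass (median -0.11, adjusted p = 0.302), although Mmp2 and Timp2, which encode a gelatinase and its inhibitor, had differences of -1.55 and -1.30.

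Lymphatic endothelial genes were also lower, with 9 of 10 tested members below both controls. Lyve1, the hyaluronan receptor gene of lymphatic vessels, had a log2 difference of -2.15 (standard error 0.25), Prox1, the transcription factor gene that specifies lymphatic identity, -1.63 (0.35), Mmrn1 -2.58 (0.65) and the chemokine gene Ccl21a, which has near-identical copies and is uncertain, -2.25 (0.48). Adjusted over the list alone 7 passed, against 0 over all genes. Together these genes passed camera (adjusted p = 1.1e-08), with an adjusted p = 0.400 with an estimated correlation. Flt4, the receptor gene of lymphatic growth, had a difference of -0.0041. Lyve1 is also a gene of resident macrophages, whose markers were lower as well.

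Endocardial genes were below both controls in 11 of 15 members (median -0.85). These 11 include Gata4, the deleted gene, at -0.61. Tbx20, a cardiac T-box transcription factor gene, had a log2 difference of -2.35 (standard error 0.44), Cytl1 -1.87 (0.39) and Npr3, the natriuretic peptide clearance receptor gene, -1.52 (0.45), while Nfatc1, Gata6 and Foxp1 had values of 0.05, 0.23 and 0.29. Adjusted over the list alone 3 passed lower, against 0 over all genes. Endocardial genes as a set passed camera (adjusted p = 1.6e-05), with an adjusted p = 0.400 with an estimated correlation, and without control 2 its adjusted p was 0.135. The venous and postcapillary list shares members with it (Vwf and Plvap), and had a median of -0.83, with 8 of 15 below both controls and 3 passing lower adjusted over the list alone. Lrg1 had a difference of -1.78 and Vcam1, a leukocyte adhesion receptor gene, -1.09. The venous list passed camera (adjusted p = 7.1e-04), with an adjusted p = 0.400 with an estimated correlation. Its adjusted p was 0.119 without control 1, 0.109 without control 2 and 0.0572 without Gata4 KO 2.

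The GATA family and cardiac transcription factor list did not pass (median -0.19, adjusted p = 0.0729), though it passed with the mean trend (adjusted p = 0.0489) and without tied genes (0.0324). It had an adjusted p = 0.400 with an estimated correlation, 0.408 with the mean trend and 0.388 without tied genes. Zfpm2, which encodes the GATA cofactor FOG2, had a log2 difference of -1.30 (standard error 0.21), Hand2 -1.31 (0.28) and Kit -0.57 (0.24). Adjusted over the list alone 3 passed lower. Gata2, which is expressed in endothelium, had a difference of 0.46 and Gata6 one of 0.23. The list includes Gata4, the deleted gene, at -0.61. Gata4, Gata6 and Tbx20 (-2.35) are also in the endocardial list.

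General endothelial genes had slightly higher values in Gata4 KO. The endothelial identity list had a median of 0.09, with 7 of 24 members above both controls, 0 below and 17 overlapping. The tight junction gene Cldn5 had a log2 difference of 1.03 (standard error 0.42; 0.55 without control 1 and 1.501 without control 2), Sox17 0.61 (0.26) and Erg 0.57 (0.24), and Pecam1, the gene of the sorting marker CD31, 0.07. The list passed camera (adjusted p = 0.0307), with an adjusted p = 0.400 with an estimated correlation. Its adjusted p was 0.2997 without control 1, 0.0707 without Gata4 KO 1, 0.0776 without Gata4 KO 2 and 0.0564 without tied genes, and its median was 0.17 without control 2. The list of VEGF, angiopoietin and Notch signalling had a median of 0.18, with 12 of 32 members above both controls, 4 below and 16 overlapping. Esm1, a VEGF-induced gene, had a difference of 1.56 (standard error 0.55; 0.77 without control 2 and 2.35 without control 1), the vasoactive peptide gene Adm 0.93 (0.22) and Notch2 -0.63. It passed camera (adjusted p = 0.0134), with an adjusted p = 0.400 with an estimated correlation. Its adjusted p was 0.0546 without control 1 and 0.170 (median 0.08) without Gata4 KO 2. In neither list did a member pass over all genes or adjusted over the list alone.

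Other endothelial lists did not pass camera. The junction and barrier list had a median of 0.22 (adjusted p = 0.0647) and of 0.14 without control 2, with Plvap, the gene of fenestral diaphragms, at -0.97. The cardiac capillary and fatty acid uptake list had a median of 0.14 (adjusted p = 0.302), with Fabp4 at 0.61 and Slc27a1 at -0.73. The arterial list had a median of 0.07 but a mean of -0.03 (adjusted p = 0.838), with the connexin gene Gja5 at -0.93 and Clu at -0.81. For leukocyte adhesion molecules and chemokines the median was -0.09 (adjusted p = 0.159), with Ccl7 at -1.58, Il6 at -1.17 and Tnf at 0.89. The list of TGF-beta, BMP and mesenchymal transition genes had a median of -0.21 (adjusted p = 0.127), with Fn1 at -0.63 and Snai2 at 0.54.

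**Figure D3:**
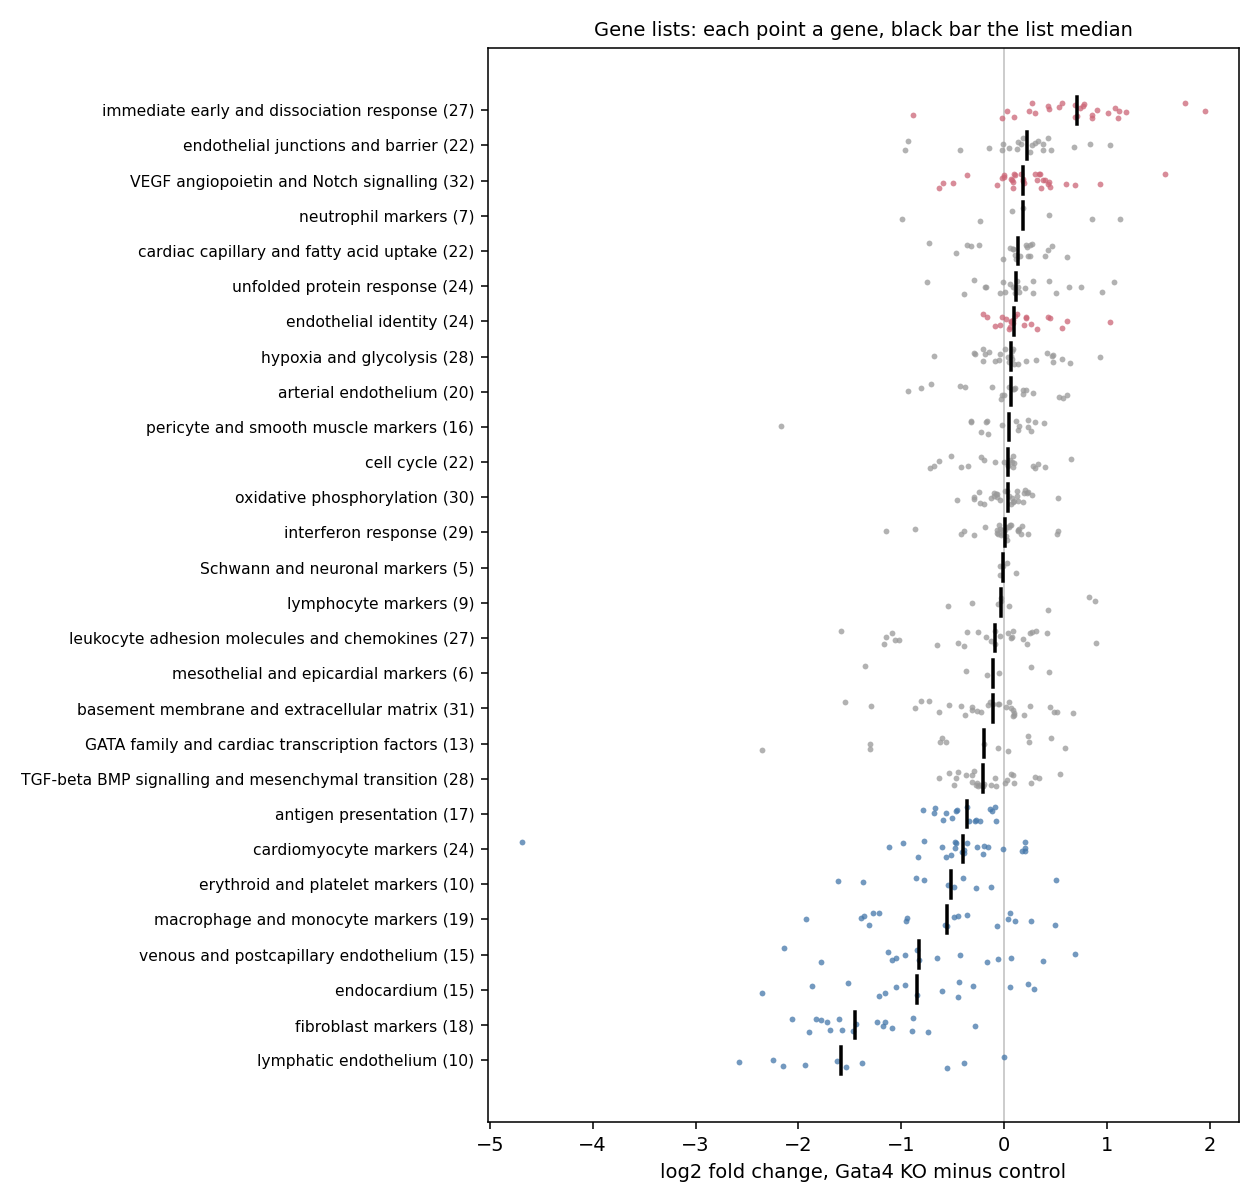
Log2 fold change, Gata4 KO minus control (x axis), of each tested member of the 28 lists (points, spread vertically at random), with the number of tested genes in brackets and list medians as black bars. Red and blue lists passed camera at a preset correlation of 0.01 as higher and lower, and grey lists did not. Medians run from -1.58 for lymphatic endothelium to 0.71 for the immediate early list.

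Immediate early and dissociation response genes were higher in Gata4 KO, with 21 of 27 above both controls and 1 below. Egr3 had a log2 difference of 1.95 (standard error 0.30), the nuclear receptor gene Nr4a1 1.76 (0.43), Btg2 1.19 (0.26) and the chaperone gene Dnajb1 1.12 (0.22). Myc had -0.89 and Fos itself 0.27 (0.31). Adjusted over the list alone 7 passed higher and 1 lower, against 0 over all genes. The list passed camera (adjusted p = 1.0e-11), with an adjusted p = 0.400 with an estimated correlation, and it passed at the preset correlation without any single library.

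Macrophage and monocyte markers were below both controls in 12 of 19 members (median -0.56). The mannose receptor gene Mrc1 had a log2 difference of -1.93 (standard error 0.32), the macrophage gene Emr1 -1.36 (0.29) and the complement gene C1qa -1.39 (0.42), while Ptprc, the pan-leukocyte gene, had -0.07 and Ctss 0.49. Adjusted over the list alone 5 passed lower, against 0 over all genes. As a set they passed camera (adjusted p = 1.6e-05), with an adjusted p = 0.406 with an estimated correlation. Antigen presentation genes were lower in 17 of 17 members, 8 of them below both controls (median -0.36), with Cd74, the invariant chain gene, at -0.79. These genes passed camera (adjusted p = 0.0018) with 0 members passing adjusted over the list alone, and had an adjusted p = 0.400 with an estimated correlation. Its adjusted p was 0.184 (median -0.21) without control 2 and 0.102 without Gata4 KO 2.

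Cardiomyocyte markers had a median of -0.40, with 12 of 24 members below both controls. Beside Myl7, the sarcomere gene Tcap had a log2 difference of -1.12 (standard error 0.24) and Myh6, the alpha myosin heavy chain gene, -0.99 (0.26), while Nppa, the atrial natriuretic peptide gene, had 0.21 (0.50). Adjusted over the list alone 1 passed, Myl7. The list passed camera (adjusted p = 7.6e-05), with an adjusted p = 0.566 with an estimated correlation, and 0.134 (median -0.13) at the preset correlation without Gata4 KO 2; its median was -0.64 without Gata4 KO 1. Erythroid and platelet markers had a median of -0.52, led by the platelet genes Ppbp (-1.61, standard error 0.33) and Gp9 (-1.37, 0.25), with 2 passing lower adjusted over the list alone. That list passed camera (adjusted p = 0.0047), with an adjusted p = 0.400 with an estimated correlation, and had 0.0546 without control 1 and 0.408 without control 2. Its median was -0.19 without Gata4 KO 2 and -0.78 without Gata4 KO 1.

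Markers of other cell types did not pass. Pericyte and smooth muscle markers had a median of 0.05 and a mean of -0.11 (adjusted p = 0.928), although the smooth muscle gene Cnn1 had a log2 difference of -2.17 and passed lower adjusted over the list alone. Lymphocyte markers had a median of -0.03 and a mean of 0.13 (adjusted p = 0.701), neutrophil markers a median of 0.18 (adjusted p = 0.348), mesothelial and epicardial markers -0.11 (adjusted p = 0.701) and Schwann and neuronal markers -0.01 with a mean of 0.01 (adjusted p = 0.928).

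Lists of general cell processes did not pass either. The unfolded protein response list had a median of 0.12 (adjusted p = 0.0729), with the stress transcription factor genes Ddit3 at 1.06 and Atf4 at 0.95 and Trib3 at -0.75. For hypoxia and glycolysis the median was 0.07 (adjusted p = 0.159), for the cell cycle 0.04 with a mean of -0.06 (adjusted p = 0.933) and for the interferon response 0.01 with a mean of -0.05 (adjusted p = 0.990), where Zbp1 was at least 2.21-fold lower. Oxidative phosphorylation genes had a median of 0.04 (adjusted p = 0.701), but differed in opposite directions without Gata4 KO 1 (median -0.23) and without Gata4 KO 2 (median 0.22). With all libraries the list had a camera adjusted p = 0.935 with an estimated correlation.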

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

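Leaving out tied genes, genes above the shared lowest value in only 1 library, or genes of chromosomes X and Y was chosen after seeing the data. The count of genes past adjusted p 0.05, 0 here, was 0 under quantile normalization, adjustment over all listed genes, without chromosomes X and Y, with a fold threshold and in each fit without 1 library. It was 27 with the mean trend of the first plan (5 higher, 22 lower), 7 under median-of-ratios scaling (2 higher, 5 lower), 51 without tied genes (9 higher, 42 lower) and 17 without genes above the lowest value in only 1 library (4 higher, 13 lower); 9 genes had an adjusted p under 0.1. Of the 51, 13 were called with the trend as well. When the p-values of all 14470 genes were adjusted over the remaining genes alone, 0 passed in both cases, so the smaller number of tests was not the cause; the prior degrees of freedom, 2.96 with all genes, were 7.75 without tied genes and 5.22 without genes above the lowest value in only 1 library. The cause of the other differences was not tested. Without 1 library, the unadjusted p of 0.05 gave 379 to 1069 genes higher and 444 to 1547 lower, Gata4 had a log2 difference of -0.78 to -0.43, and 7 to 11 of the 28 lists passed, against 11 in all, 4 of which passed in each such fit. With an estimated correlation, where camera uses only the 2 residual degrees of freedom, 0 lists passed and with fry 0. In the authors' deposited table, 15 genes were higher and 56 lower at a log2 fold change of at least 2. Scaling kept the sign of the list medians but for Schwann and neuronal markers (0.0019 under median-of-ratios scaling).

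Without 1 library, medians reached 0 or changed sign for these lists: GATA family and cardiac transcription factors (-0.47 to 0.031), leukocyte adhesion molecules and chemokines (-0.27 to 0), basement membrane and extracellular matrix (-0.28 to 0.10), cell cycle (-0.039 to 0.063), interferon response (-0.071 to 0.075), oxidative phosphorylation (-0.23 to 0.22), pericyte and smooth muscle (-0.16 to 0.07), lymphocyte (-0.070 to 0.29), neutrophil (-0.10 to 0.38), mesothelial and epicardial (-0.22 to 0) and Schwann and neuronal (-0.014 to 0). So did the log2 differences of Mcm5 (-1.47 to 0.093), H2-DMb1 (-1.74 to 0.36), Trac (-0.067 to 1.72), Sox10 (0 to 0.22) and Kcna1 (-0.081 to 0). Medians also moved by over 1.5 times without 1 library for the lists of cardiac capillary (0.041 to 0.16), arterial (0.015 to 0.17), junction (0.14 to 0.40), TGF-beta and BMP (-0.26 to -0.093), unfolded protein response (0.025 to 0.24) and hypoxia genes (0.023 to 0.12). Of the named genes, 23 moved as much and 52 did not; the 23 include Mmrn1 (-3.53 to -1.63), Ccl7 (-2.26 to -0.91), C1qa (-1.88 to -0.91), Sox17 (0.41 to 0.82), Fabp4 (0.26 to 0.96), Snai2 (0.26 to 0.82) and Ddit3 (0.62 to 1.503). Another pseudocount, a minimum value of 5 and the highest row per symbol were not run, since centred values keep no level, and the deposited table holds no p for a stricter threshold. No paired analysis was possible because the labels give the groups no shared replicate numbers. Sequencing depth is unknown, so its limits could not be stated.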

Other observations

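The gene groups in this and the next paragraph were chosen after values were seen, and no test was run on them. Complement genes had lower values in Gata4 KO, with 10 of 12 below both controls and a median log2 difference of -1.35; 3 of the 12 are also in the macrophage list. C3, the central complement component gene, had a difference of -3.14 (standard error 0.45) and C4b was at the lowest value in both Gata4 KO libraries. Genes of tissue-resident macrophages had a median of -1.83, with 10 of 11 below both controls, among them Wfdc17 at -2.79, F13a1 at -2.00 and Retnla at -1.83. The general leukocyte gene Ptprc had -0.07.

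Single genes outside the fixed lists with low values in Gata4 KO were Dkk3 at a log2 difference of -3.56, the acute phase gene Serpina3n at -2.82, Efemp1 at -2.61 and Tnxb at -2.15. Of 276 small nucleolar RNAs tested, 29 were higher and 11 lower at an unadjusted p of 0.05. Their share of 14.5% stood beside 8.12% over all genes, 13.4% in lincRNAs and 15.1% in the annotation class of miscellaneous RNAs, and their libraries differed more within groups (median 0.48 against 0.29 in protein-coding genes). The controls differed from each other by a root mean square of 0.607 log2 units and the Gata4 KO libraries by 0.517, against 0.619 to 0.653 between groups. By the median absolute difference the controls stood farthest apart, at 0.354, with 0.297 to 0.339 between groups and 0.246 between the Gata4 KO libraries. Both Gata4 KO values lay above both controls in 2271 genes and below in 2502. These are 17.6% and 19.4% of the 12905 genes not tied in 3 libraries, where chance gives 16.7% each. The real split separated 4773 genes in all and the other splits 3686 and 4446.

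Of the explanations below, the tests on X-linked escape genes and on atrial genes were written before their values were seen and the others after. The first pattern is that Xist and the Y-linked genes separate the groups. A rise of Xist from loss of Gata4 in animals of the same sex is argued against by 4 Y-linked genes, at their lowest value in both Gata4 KO libraries and above it in both controls. Animals of different sex in the groups would raise Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation, and their median log2 difference was 0.83 (0.829, SD 0.12), with all 4 above both controls. Together these transcripts show the pattern of male controls and female Gata4 KO animals, although the labels give no sex. Sex thus followed the groups. Every other difference between the groups may hold a part of sex as well as of genotype, and the design cannot tell them apart.

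The second pattern is that markers of fibroblasts, macrophages, cardiomyocytes and lymphatic endothelium were lower in Gata4 KO. A lower share of endothelial cells in the control sorts would raise markers of whichever other cells were held there, not of all cell types alike. The pericyte and smooth muscle median lay 1.502 log2 units above that of fibroblasts (0.99 to 1.97 without 1 library). A permutation p of 3e-05 covers only the choice of genes, as if independent. The gap argues against an equal carry-over of all other cell types, but cannot exclude a lower endothelial share through fibroblasts or macrophages. Such a lower share would also leave endothelial genes higher in Gata4 KO. The endothelial identity list lay slightly in that direction (median 0.09), with 7 of 24 members above both controls, 0 below and 17 overlapping. The gate on eGFP and CD31 is meant to remove both pericytes and fibroblasts. Yet 17 of 18 fibroblast and 16 of 16 pericyte and smooth muscle markers had no tied libraries. The gate alone therefore cannot exclude carried-over transcripts. More atrial tissue in the control preparations may account for Myl7 and Sln, which are atrial, although the cells were isolated from ventricles. The gate is meant to remove cardiomyocytes, yet 23 of 24 cardiomyocyte markers had no tied libraries. The 5 other atrial genes tested had a median of -0.69 (SD 0.46), between the bounds set beforehand, with Nppa at 0.21. Bmp10, Sbk2, Mybphl and Kcnj3 had the same value in all 4 libraries, and ventricular genes had a median of -0.40. With so few genes, more atrial tissue in controls and genotype cannot be told apart for Myl7 and Sln. Fibroblast or macrophage material carried over in the controls, a loss of these transcripts with Gata4 and the sex of the animals stay open and untested, and levels needed to judge a carried-over share are lost to centring.

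The third pattern is that immediate early genes were higher in Gata4 KO. Stress chaperones, 4 of which are in that list, had a median of 0.64 (SD 0.28), and the 7 outside it a median of 0.60. A difference in tissue dissociation or sort handling could raise both sets, but the chaperones were chosen after values were seen and handling would have followed the groups, so handling and genotype cannot be told apart here. A response to Gata4 loss was not tested. For the number of genes at an unadjusted p of 0.05, the real split of the 4 libraries gave 1175 and the highest of the other splits 530, so 1 of the 3 splits gave as many; 3 splits are too few for a share under 0.05.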
